A study of Drosophila melanogaster with 2 samples.

How the data were processed

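Total genomic DNA was sequenced from 2 groups of Drosophila melanogaster, with 1 library each. The first group was salivary glands dissected by hand from male larvae of the third instar, and the second was embryos of 0 to 6 hours. Both came from a yellow white stock grown at 25 °C. Per the labels' protocols, DNA was sheared to a mean of about 200 bp before library preparation. Bowtie2, Picard and deepTools version 1.5.8.1 and the genome build dm3 are named in the submitters' processing notes. The order of these steps, the treatment of reads that align to several places, and any duplicate filter are not given in the sources used here. Reads from repeated sequence could therefore be shared among copies or left out, which can affect heterochromatin and other repeated sequence.

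The deposited files give read coverage as 1 signal value per 15 kb window for 15 sequences of the assembly. These are the arms 2L, 2R, 3L and 3R, chromosomes X and 4, the heterochromatin sequences 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, the unplaced sequences U and Uextra, and the mitochondrial genome M. Neighbouring windows of equal value were merged in the deposited files and were separated again here, giving 11242 windows per library. The last window of each sequence can be longer than 15 kb. The deposited coverage had been scaled to nearly the same total in both libraries, 2442050 in the gland and 2440880 in the embryo.

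The depth was read from the values. Outside the last windows, 99.8% of the nonzero gland values were whole multiples of 0.348 and 99.8% of the embryo values were whole multiples of 0.166, within 0.006. By chance 3.45% and 7.23% would be. Taking each step as 1 read gave 7011518 reads in the gland windows and 14697122 in the embryo windows, with a median of 939 and 1485 reads per window on the autosomal arms. This depth is inferred from the values and is not stated by the labels. Too few windows have low values for a check by them that the step is 1 read, so no count test was run. The inferred reads serve for thinning and for intervals of ratios, which would change if the step were not 1 read. Those are exact Clopper-Pearson 95% intervals with the same pseudocount added to the bounds as to the ratio, and they cover counting error only. The pseudocount raises the lowest ratios. Intervals of shares of windows are 95% Wilson intervals, and those of medians are 95% intervals from binomial order statistics over windows. Windows of 1 chromosome are not independent, so the intervals over windows are too narrow.

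Each library's value was divided by its median over 2L, 2R, 3L and 3R, a pseudocount of 0.01 of that median was added, and the gland was divided by the embryo. The result, the relative copy, was set to a median of 1 over these 4 arms. Windows with an embryo value under 0.25 of the arm median were left out, which removed 15 of 8023 windows on the 6 chromosomes and 61 of 593 windows on the heterochromatin sequences other than Y. For calling domains, X was centred on its own median, since glands were from males and the sex of the embryos is not given. Chromosome 4 was also centred on its own median, so a lower copy of the whole chromosome is not called. The median a window is set against is called the reference median. It is that of 2L, 2R, 3L and 3R together, or of X or 4 alone. A window was called low at a relative copy of 0.7 or less, low windows up to 20 kb apart were joined, and joined runs of at least 50 kb were called domains. The deficit of a domain is the sum over its windows of 1 minus the relative copy, times the length in kb. The mirrored rule, a relative copy of 1.3 or more, gave stretches of high copy. It was planned as a background of how many domains the rule calls by scatter. The thresholds of 0.7 and 1.3 are equally far from 1 on the linear scale, but on the log2 scale 1.3 is nearer.

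Tested on simulated data with 60 planted domains among 8023 windows, the rule recovered 20 of 20 at a copy of 0.2, 20 of 20 at 0.4 and 19 of 20 at 0.6, with 0 false domains. The simulated noise was 0.1 on the log2 scale and independent between windows, whereas the SD of windows outside the called domains was 0.267. Such noise can hardly put neighbouring windows at 0.7 or less together, and 0 stretches of high copy were called too. The 0 false domains therefore do not tell how many domains broad variation along the arms would give. X planted at 0.7 was recovered at 0.702.

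With 1 library per group no test between the groups was made, and no p-value is given. The spread quoted is that between windows of a library. Design, alternatives and gene lists were fixed before the data were examined, except where a choice is said to be later. The running median of 2 Mb as baseline, the removal of a trend on embryo coverage, the thinning of the embryo reads the omission of last windows, the omission of the pseudocount and the split of domains by length at 200 kb were added after seeing the data. The rule for naming regions takes the 15 domains with the largest deficit outside the 2 Mb next to the centromere, the 3 largest within it, and the 5 largest stretches of high copy. The comparisons of 12 gene lists and of the gene content and base composition of domains were planned only for an annotation of the same build. The gene table at hand is of Release 6, so genes were not placed on these coordinates and those comparisons were not run. Alternatives covered the threshold, embryo minimum, centring, scaling, smoothing, pseudocount, denominator, domain length and joining distance. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.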

Results

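DNA copy along the genome was compared between the polytene salivary glands of male larvae and early embryos of the same stock. Polytene chromosomes are giant chromosomes made by repeated rounds of DNA replication without cell division, and parts of them are known to be replicated less than the rest. Embryos, which replicate normally, served as the control in this design. Each group had 1 library, so no difference below has a replicate check, and every interval covers counting error or the spread of windows within these libraries. The gland windows held 7011518 reads and the embryo windows 14697122, as inferred from the steps of the deposited coverage.

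The gland profile was uneven along the chromosome arms, whereas the embryo profile was close to flat. The 5th to 95th percentile of windows on 2L, 2R, 3L and 3R ran from 141.75 to 456.61 in the gland and from 217.07 to 271.54 in the embryo, in deposited coverage. On the log2 scale the SD across these windows was 0.61 in the gland and 0.14 in the embryo. The relative copy of the gland over the embryo had an SD of 0.56 across windows of these arms on the log2 scale. The noise of single windows, estimated from the differences between neighbours, was 0.11. It is a scaled median absolute deviation, which gives little weight to large steps, so it is not the same measure as the SD of 0.56.

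**Figure D1:**
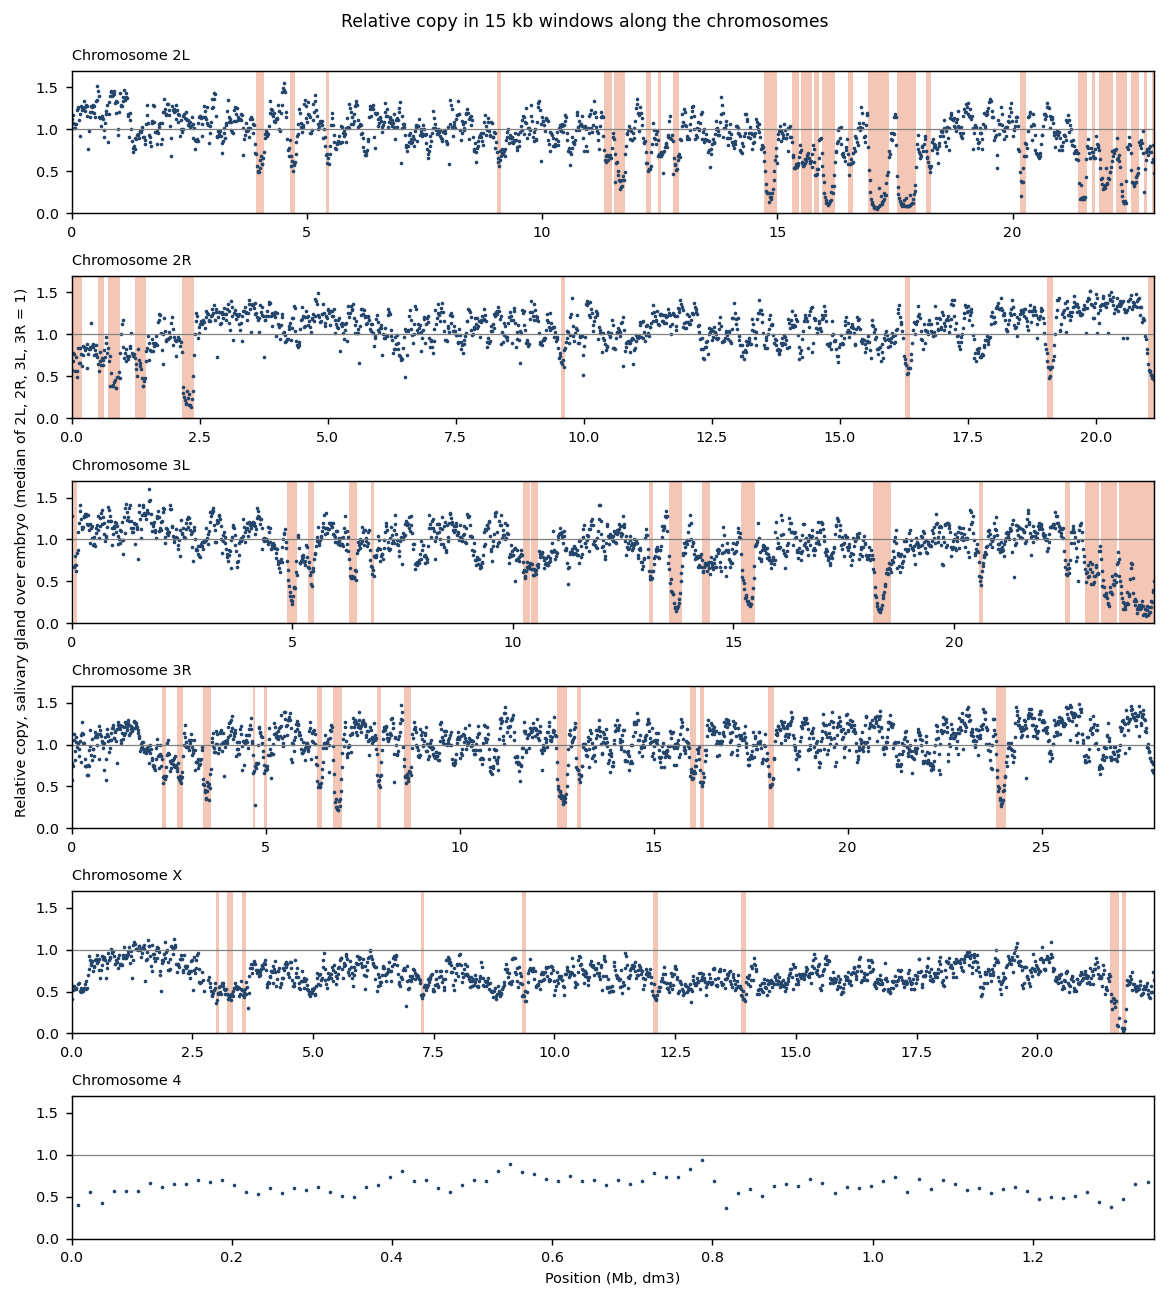
Relative copy (gland over embryo, y axis, linear, median of 2L, 2R, 3L and 3R set to 1) of each 15 kb window (points) against position in Mb of dm3 (x axis, scaled separately per chromosome) for 6 chromosomes, with the 76 low-copy domains as shaded bands. Deep troughs are most frequent on 2L and 3L, and X and 4 lie below the autosomal arms as a whole.

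The question the series set was which regions are replicated less in the gland. In all, 76 low-copy domains were found on the 6 chromosomes, covering 12.8 Mb or 10.7% of their length. Arm 2L held 26 of them over 4.38 Mb, 19.0% of the arm, and 3L held 17 over 3.93 Mb, 16.0% of the arm. The other arms held fewer, with 15 domains over 7.85% of 3R, 9 over 6.72% of 2R and 9 over 4.01% of X. Chromosome 4 had 0 domains once it was centred on its own median. On the scale of the autosomal arms its median was 0.628, under the threshold of 0.7, so the 0 rests on the centring. Domain lengths ran from 60 to 799 kb with a median of 135 kb. Domain means ran from 0.157 to 0.701 of the reference median (2L, 2R, 3L and 3R together, or X alone). Of the 76, 23 had a mean below 0.5, and 17 had a lowest window at 0.25 or less. Their summed deficit was 6.65 Mb relative to an even copy. As a background of how many domains the rule calls by scatter, the mirrored rule called 49 stretches of high copy over 5.33 Mb. The 76 are therefore not all shown to be regions of lower replication.

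The embryo alone, put through the same rule against its own reference medians and with no pseudocount, gave 5 low domains of 300 kb in total. Of these, 2 overlapped the 76. The gland alone, treated in the same way, gave 92 low domains, of which 70 overlapped the 76. Windows inside the domains had a median embryo coverage of 0.966 of their reference median and a median gland coverage of 0.510. The number of domains depended on the threshold and the scale. It was 26 at a threshold of 0.5, 125 at 0.8 and 45 with values as deposited, without scaling or centring. With X and 4 centred on the autosomal arms it was 127, which also takes in the dose of X, whose median on that scale was 0.681.

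The deepest troughs away from centromeres lay on 2L. The domain at 2L 17535001 to 17955000 had a mean relative copy of 0.176 ± 0.117 (SD, n = 28 windows), and its lowest window stood at 0.0803 (counting interval 0.0646 to 0.0991). Close by, 2L 16935001 to 17370000 averaged 0.209 ± 0.164 (SD, n = 29 windows) and reached 0.0530 (0.0406 to 0.0689), the lowest value on 2L, 2R, 3L and 3R. That window rested on 40 inferred gland reads and 1449 inferred embryo reads, and with no pseudocount it stood at 0.0434 (0.0309 to 0.0594). The domain at 2L 15945001 to 16230000 averaged 0.269 and reached 0.103 (0.0836 to 0.126). Further along the same arm, 2L 14715001 to 15000000 averaged 0.383 with a lowest window of 0.136, and 2L 11535001 to 11760000 averaged 0.446 with a lowest window of 0.287. The domain at 2L 15510001 to 15735000 was shallower, at 0.621 ± 0.0464 (SD, n = 15 windows), and its embryo coverage was also low, at 0.794 of the arm median. Against a running median of 2 Mb, a baseline chosen after seeing the data, the mean of that domain was 0.956 and that of 2L 16935001 to 17370000 was 0.374. Other low-copy domains lie within that span and lower the baseline there.

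**Figure D2:**
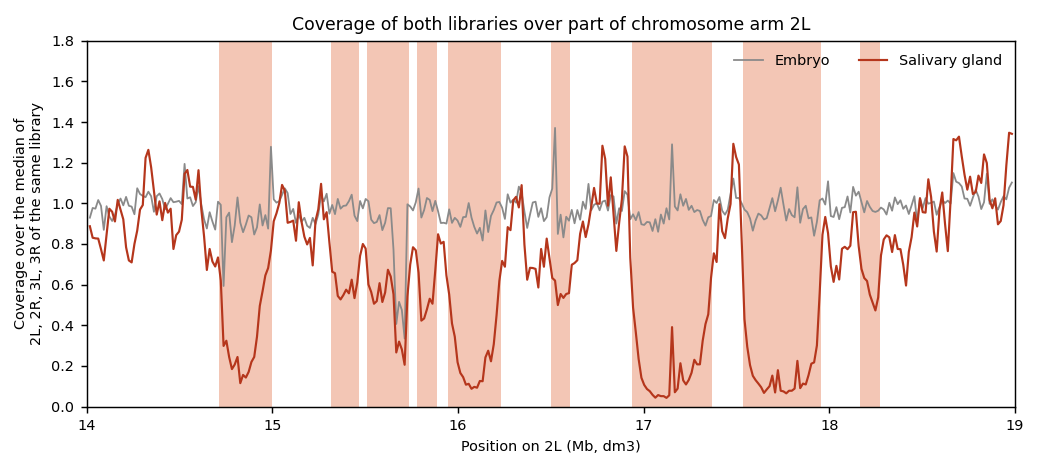
Coverage of the gland (red) and the embryo (grey) over 2L from 14 to 19 Mb of dm3 (x axis), each divided by its own median over 2L, 2R, 3L and 3R (y axis, linear, from 0), with low-copy domains shaded. The gland falls below 0.2 in 4 of the 9 shaded domains, where the embryo has a median of 0.905 or more, and both libraries dip in the domain starting at 15510001, to 0.206 in the gland and 0.335 in the embryo.

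Arm 3L carried 4 of the 15 largest distal domains, that is, domains outside the 2 Mb next to the centromere. The longest, 3L 18165001 to 18570000, averaged 0.407 ± 0.20 (SD, n = 27 windows) and fell to 0.133 (0.110 to 0.159). The domains at 3L 13545001 to 13845000 and 3L 15180001 to 15480000 averaged 0.356 and 0.375, with lowest windows of 0.150 and 0.209. The domain at 3L 4890001 to 5115000 averaged 0.441 and reached 0.234. On 3R the domain at 12510001 to 12780000 averaged 0.420 ± 0.0949 (SD, n = 18 windows), with a lowest window of 0.291 (0.257 to 0.329). Copy was lower in the domain at 3R 6750001 to 6960000, which averaged 0.351 and reached 0.221. The domains at 3R 23835001 to 24075000 and 3R 3375001 to 3585000 averaged 0.457 and 0.484. On 2R the single one of the 15 lay at 2160001 to 2385000, just outside the 2 Mb next to the centromere. It averaged 0.258 ± 0.10 (SD, n = 15 windows), reached 0.131 (0.109 to 0.157), and had an embryo coverage of 0.837 of the arm median. None of the 15 lay on X, where the 7 distal domains had lowest windows of 0.525 to 0.639 of the X median.

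Longer domains tended to have lower minima. Across the 59 distal domains, the rank correlation between length and the relative copy of the lowest window was -0.63 (Spearman's rho). Domains are parts of 1 pair of libraries and not independent replicates, and a fixed threshold links length to depth by construction, so no p-value is given. The 15 distal domains of 200 kb or more had a median lowest window of 0.209, within a range of 0.0530 to 0.546. The 44 shorter ones had a median of 0.535, within a range of 0.207 to 0.681.

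**Figure D3:**
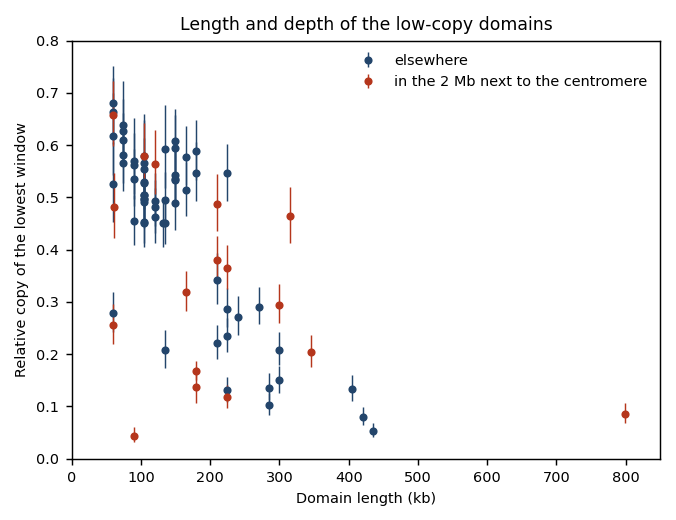
Relative copy of the lowest window (y axis, linear, from 0, chromosome median set to 1) against domain length in kb (x axis) for the 76 low-copy domains, those in the 2 Mb next to the centromere in red and the others in blue, with bars for 95% counting intervals. Distal domains of 200 kb or more have a median of 0.209 and shorter ones a median of 0.535.

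Copy was also lower next to most centromeres. In the 2 Mb of each arm next to the centromere, 36.4% of windows were low (95% Wilson interval 32.8% to 40.2%, n = 659 windows), against 9.74% (9.08% to 10.4%, n = 7198 windows) of the windows outside both ends. The arms differed. The share was 73.7% on 3L, 51.9% on 2L, 33.8% on 2R and 18.1% on X. On 3R it was 3.76% (1.62% to 8.50%), against 9.51% in the rest of that arm, and the median copy of that side was 1.06. The largest deficit of any domain was at 3L 23745001 to 24543557, the assembled end of the arm, with a mean of 0.282 ± 0.157 (SD, n = 53 windows) and a lowest window of 0.0857 (0.0680 to 0.107). It was preceded by 3L 23340001 to 23685000, at a mean of 0.415 ± 0.119 (SD, n = 23 windows). Against the running median of 2 Mb these 2 domains averaged 0.806 and 0.804. With 73.7% of the windows on this side of 3L low, that baseline is itself low there, so these values say little about the 2 domains. On 2L the centromere-side domain with the largest deficit lay at 21840001 to 22140000, at a mean of 0.463 ± 0.135 (SD, n = 20 windows). The domain at X 21750001 to 21840000, picked out after its values were seen, averaged 0.157 of the X median and reached 0.0425 (0.0310 to 0.0597), or 0.0266 (0.0149 to 0.0441) with no pseudocount. With the centromere side set at 4 Mb the low share was 23.6%, and at a threshold of 0.5 it was 20.8%.

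The 200 kb next to the telomeres had 24.6% low windows (15.5% to 36.7%, n = 61 windows). On 2R these were 8 of 13 windows, and on 2L 0 of 13 windows, for which the Wilson interval reaches 22.8%. The last domain of 2R, at 21015001 to 21146708 and likewise picked out after its values were seen, averaged 0.538. At a threshold of 0.5 the telomere share was 3.28%, against 3.31% in the remainder of the arms.

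The assembled heterochromatin, the repeat-rich chromatin around centromeres and on Y, had a far lower copy than the arms. Over 2LHet, 2RHet, 3LHet, 3RHet and XHet together the median relative copy was 0.202 (95% interval 0.175 to 0.227, n = 532 windows), and 79.5% of windows were at 0.5 or less. The lowest of these was 3RHet, with a median of 0.117 (0.0955 to 0.134, n = 152 windows). The medians of 2RHet and 3LHet were 0.231 and 0.239, and those of 2LHet and XHet, with 20 and 13 windows, were 0.445 and 0.420. YHet stood at 0.144 (0.122 to 0.187, n = 10 windows), on the scale of the autosomal arms and with 13 of its 23 windows left out for low embryo coverage. XHet and YHet are not corrected for the sex of the animals, so their values also hold the dose of X or Y. XHet is therefore not directly comparable with 2LHet. The unplaced sequences U and Uextra had medians of 0.111 and 0.142. In the windows kept, embryo coverage of 2RHet, 3LHet and 3RHet was close to that of the arms, with medians of 237, 237 and 233 against 246.63. Windows with low embryo coverage had been left out first, 32 of 219 on 2RHet, 10 of 170 on 3LHet and 15 of 167 on 3RHet, which raises these medians. How reads from repeats were placed is not given, so values on these sequences depend on an alignment rule that is not known.

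**Figure D4:**
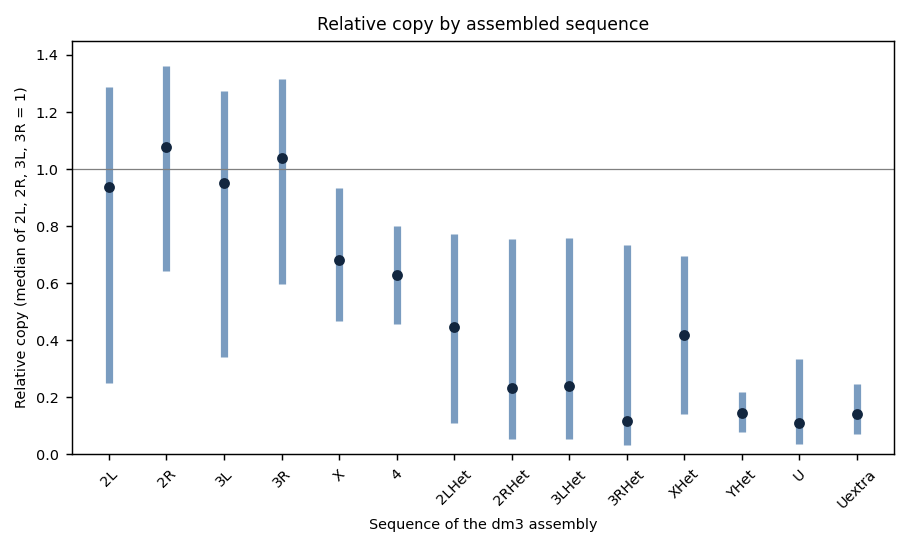
Median relative copy (points) and the 5th to 95th percentile of windows (bars) for 14 assembled sequences (x axis), with the median of 2L, 2R, 3L and 3R set to 1 (y axis, linear, from 0). X and 4 have medians of 0.681 and 0.628, and the heterochromatin and unplaced sequences have medians of 0.445 or less. X, XHet and YHet are not corrected for the sex of the animals.

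Chromosome 4, the small and largely heterochromatic autosome, was lower than the arms as a whole. Its median relative copy was 0.628 (0.603 to 0.653, n = 90 windows), and 100% of its windows were below the arm median, with a range of 0.364 to 0.942. In the embryo its coverage was 1.01 of the arm median, and in the gland 0.629. The median of X was 0.681 (0.673 to 0.692, n = 1481 windows). X coverage was 0.491 of the arm median in the male glands and 0.729 in the embryos, whose sex is not given. Males have a lower dose of X than females, so the lower median of X can follow from sex and does not by itself show lower replication. The 4 autosomal arms also differed from one another, with medians of 1.08 on 2R, 1.04 on 3R, 0.951 on 3L and 0.935 on 2L. Whether an arm lay above or below 1 depended on the scale, since with values as deposited 3L stood at 1.27 and 2L at 1.25, and 2R and 3R at 1.44 and 1.39.

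The mirrored rule gave 49 stretches of high copy over 5.33 Mb, with means of 1.28 to 1.52 of the reference median and a highest window of 1.66. Of these, 15 lay on X and 14 on 2R. The 3 largest on X, at 1275001 to 1515000, 1545001 to 1815000 and 1050001 to 1245000, averaged 1.49, 1.40 and 1.38 of the X median. On the scale of the autosomal arms they stood at 1.02, 0.954 and 0.941. With X and 4 on that scale 34 stretches were called, and no window of X reached 1.3, the highest being 1.13. That scale also holds the dose of X, so the stretches on X rest on centring X on itself. The stretches at 2R 20625001 to 20895000 and 2R 20085001 to 20355000 averaged 1.38 and 1.37 of the arm median. The number of stretches ran from 19 with a minimum length of 100 kb to 211 with values as deposited. High stretches outnumbered low domains with a minimum length of 20 kb (119 against 107) and with no denominator (91 against 90). They also did so with values as deposited (211 against 45) and with the low threshold alone set to 0.5 (49 against 26). These last 2 comparisons do not weigh low domains against a background. Values as deposited multiply copy on the 4 arms by 1.33, which favours high stretches, and the other moved only the low threshold. Against the running median of 2 Mb 31 stretches of high copy were called, and 4 of the 49 were overlapped by one. With a trend on embryo coverage removed, a step also added after seeing the data, 31 were called, 20 of the 49 were overlapped by one, and 2R 20625001, X 1545001 and X 1050001 averaged 1.23, 1.29 and 1.27.

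Mitochondrial DNA had a higher coverage in the embryo. Its window had 12.6 times the value of the median arm window in the embryo and 0.521 times in the gland, a relative copy of 0.0418 (0.0382 to 0.0456). It is the last window of its sequence, 19.5 kb long, and whether its value counts the whole extent is not given, so both multiples of 15 kb windows are uncertain.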

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

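The 2 Mb running median, the removed embryo trend, the thinned embryo, the omitted last windows and the omitted pseudocount were chosen after seeing the data. The 76 low-copy domains became 26 at a threshold of 0.5, 125 at 0.8, 127 with X and 4 centred on the arms, and 45 with values as deposited. The other alternatives gave 58 to 107. Low windows, 12.0% of the 6 chromosomes, became 4.71% and 20.8% at those thresholds, 21.8% with X and 4 on the arms, 7.38% as deposited, 10.9% with a running median of 5 windows, 10.0025% with a pseudocount of 0.1, 14.5% with no denominator, 9.40% against the 2 Mb median and 10.3% without the embryo trend. Values as deposited drop both the scaling and the centring. Copy on the scale of the arms rises by 0.42 on the log2 scale, while domains and stretches of X and 4, otherwise set against their own medians, are multiplied by 0.909 and 0.838. The median copy was then 1.25 on 2L and 1.27 on 3L, above 1 instead of below it, and 1.44 on 2R, 1.39 on 3R, 0.909 on X, 0.838 on 4, 0.269 on the Het sequences without Y, 0.193 on YHet, 0.148 on U, 0.189 on Uextra and 0.0557 on M. Means in place of medians gave 0.713 on X, 0.297 on Het, 0.143 on U and 0.153 on Uextra. Without the domains, medians were 0.962 on 2L and on 3L, 1.02 on 3R and 0.666 on X. The centromere-side share of 36.4% was 47.6% within 1 Mb, 23.6% within 4 Mb and 20.8% at a threshold of 0.5, where the telomere side and the rest had 3.28% and 3.31%. The 18 named low domains were picked for the largest deficits in these data. All lie on 2L, 2R, 3L or 3R, where centring X and 4 on the arms changes nothing, and the threshold settings were not applied to them. Of 234 values of these 18, 230 stayed at 0.7 or less. The exceptions were 2L 15510001 as deposited (0.828) and against the 2 Mb median (0.956), and 3L 23745001 and 3L 23340001 against that median (0.806 and 0.804). Around these domains the 2 Mb median is itself lowered by low-copy domains. With X on the arms, a scale that also holds the dose of X, the named high stretches X 1545001 and X 1050001 fell below 1 (0.954 and 0.941). Of 65 values of the 5 named ones 13 were below 1.3. Apart from these factors of the deposited scale, the cause of the changes was not tested. Embryo reads thinned to the gland depth gave 78 domains, and no pseudocount gave 77. Alternatives for the gene lists and the domain content were not run, since no annotation of the build was used here.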

Other observations

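The tests of embryo coverage in the domains and of neighbouring windows were chosen after the results were seen, as was the use of values with no denominator, themselves fixed earlier, to weigh an explanation. The 2 Mb running median and the removal of the embryo trend were added after seeing the data. The regions in the next sentences were also picked out after their values were seen. The heterochromatin sequences were not evenly low. On them, 9 stretches of at least 60 kb had a relative copy of 0.6 or more in every window, 874 kb in all. The longest, 2RHet 3135001 to 3288761, averaged 0.784 ± 0.104 (SD, n = 10 windows), and 3LHet 2370001 to 2490000 averaged 0.755 ± 0.0791 (SD, n = 8 windows). On 3RHet, whose median was 0.117, the stretch at 1860001 to 1965000 averaged 0.721 ± 0.0309 (SD, n = 7 windows). The embryo coverage of these 3 was 1.07, 0.949 and 1.09 of the arm median.

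Some sequence with high embryo coverage had a low relative copy. On 2L, windows were picked for lying in a low-copy domain and having an embryo coverage over 2 times the arm median, so their low copy was a condition. These 7 windows, between 21420001 and 21540000, had a median embryo coverage of 2.20 of the arm median. Their gland coverage was 0.378 and their relative copy 0.175. On U, windows were picked for an embryo coverage over 4 times the arm median only. These 2 windows, at 5280001 to 5310000, had an embryo coverage of 8.32 and a gland coverage of 0.502 of the arm median, a relative copy of 0.0611. Genes were not placed on either. All 5 regions that were called low on the embryo values were also low in the gland. Of these, 2L 15660001 to 15720000 and 2R 2235001 to 2295000 lie within named low-copy domains, with the embryo at 0.433 and 0.566 of the arm median, the gland at 0.268 and 0.114, and a relative copy of 0.626 and 0.223. At 3L 19710001 to 19770000, X 2685001 to 2745000 and X 19800001 to 19860000 the embryo stood at 0.609, 0.570 and 0.564 of its reference median and the gland at 0.535, 0.532 and 0.542, over 4, 3 and 4 windows, with a relative copy of 0.897, 0.923 and 0.946.

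The first pattern weighed was the set of 76 low-copy domains. Sequence on which few reads can be placed would lower both libraries, and such a loss cancels in the ratio on which the domains were called. The embryo median of 0.966 of the reference median in these windows was therefore partly set by the calling and does not decide on this explanation. Each library alone, with no ratio, gave 92 low domains in the gland and 5 in the embryo, so most low gland domains had no low embryo domain. Counting error of single windows would leave neighbours unrelated, whereas the log2 copy of neighbouring windows correlated at 0.919 across windows of 1 pair of libraries, which are not independent replicates. The tables also argue against a library trend that follows embryo coverage as the whole cause, since 57 of the 76 were still overlapped by a domain after it was removed. Underreplication in the polytene gland, the difference the design names, stays open as untested, and so does a base composition bias of a library, which was not analysed here.

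The second pattern was the 49 stretches above the reference median. An uneven embryo denominator would remove them when the gland value is used with no denominator, but 91 stretches were then called and 49 of the 49 were overlapped by one. A library trend that follows embryo coverage stays open for part of them, since 31 stretches were called after it was removed and 20 of the 49 were overlapped by one. Against a running median of 2 Mb, 4 of the 49 were overlapped by a stretch, whereas 55 of the 76 low-copy domains were overlapped by a domain. The stretches at 2R 20625001 and 2R 20085001 averaged 1.03 and 1.04 against it. Stretches that lie close together raise that baseline themselves, so there it cannot tell separate stretches from a broad crest. Broad regional variation in the gland therefore stays open, and many of the 49 may be crests of variation over a wider region. Whether that variation is a property of the polytene gland or a base composition bias was not tested.

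The third pattern was the slope of the domain flanks. Of the 30 flanks of the 15 largest distal domains, 3 on 2L ran into other low-copy domains, both of 2L 15510001 and the left one of 2L 15945001, and were left out after this was seen. On the other 27, copy returned to 0.9 of the median of 2L, 2R, 3L and 3R together after a median of 180 kb from the lowest window. The range was 75 to 330 kb. A sharp border blurred by the window size would put the middle 50% of the rise within 15 kb, but it took a median of 60 kb, with quartiles of 37.5 and 75 kb, and 15 kb or less on 1 of the 27. No biological explanation of the slope was tested.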
